A study of Mus musculus with 11 samples.

How the data were processed

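The series holds 11 liver arrays from C57BL/6J mice, each from 1 mouse per the labels: 4 control, 4 high-fat and 3 fasted. Control mice ate chow with 6.5% fat for 10 weeks. High-fat mice ate a diet with 42.16% fat for 10 weeks, and fasted mice ate that diet and then went without food for the last 48 h. Per the labels the study groups held 9, 5 and 4 mice, so not every mouse has an array here. Per the labels liver RNA was labelled with Cy5, and a universal mouse reference RNA, the same for all arrays, with Cy3, both during reverse transcription. The 2 channels were read on 1 array per mouse.

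The values the authors deposited are log ratios of liver over reference, taken here as log2. The base of the logarithm, the hybridisation, the scanner, the background correction, the normalisation within an array and the rule that left most cells empty are not given in the sources used here. If the base was another, every log2 change is off by 1 constant factor and the tests are unaffected. The table has 17280 rows, each taken here as 1 spot, of which 3864 to 5567 per array hold a value. Array medians lay between 0.07 and 0.47, so the deposited arrays were not centred on 0. Intensities are not used here, so signal over background is unknown, and the number of arrays limits the precision.

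Gene symbols came from the platform's table of spots and genes. Of the spots, 14718 carry 1 symbol, 1 carries several and 2561 carry none. The gene identifiers of 14445 of the spots with 1 symbol matched the current gene table, and 0 symbols needed an update. The sources used here pair the spots with no genome build, so no coordinates are given.

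High-fat array 4 was left out. This was decided after the values had been looked at and departs from the design fixed before, which had all 11 arrays in 1 fit. Its correlation with each of the other arrays lay between -0.03 and 0.01, and hepatocyte genes did not stand out on it. It is therefore in doubt whether its values belong to the genes listed for its rows. Counts with all 11 arrays stand beside the main counts. A planned check that gives each contrast its own high-fat arrays could not be run with 3 of them.

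Each of the 10 arrays was centred on its median. Spots with the same single symbol were averaged over those filled on an array, and spots without a symbol were kept as they were. Genes with a value on at least 2 arrays of every group were tested, 3558 in all, of which 3169 have a symbol, 389 have none and 173 average more than 1 spot. A value was present on all 10 arrays for 2262 of them. Linear models with empirical Bayes shrinkage were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and a common spread, and 3 contrasts were taken: high-fat minus control, fasted minus high-fat and fasted minus control. All tests were two-sided. P-values were adjusted by the Benjamini-Hochberg method within a contrast, and a gene was called at an adjusted p under 0.05. An F test over the group means was adjusted in the same way. The residual degrees of freedom were 7 for a gene filled on all 10 arrays, with 4.96 prior degrees of freedom.

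Fixed beforehand were 33 lists, of metabolic and cellular pathways and of cell-type markers. The 23 lists with at least 4 tested members were compared with all other genes by limma's camera on the moderated statistics, with a preset correlation of 0.01, and p-values were adjusted over the 69 tests. The camera tests were repeated on the same members with a correlation estimated for each list, with negative estimates set to 0. That correlation came only from members filled on all 10 arrays, 13 of 23 for xenobiotic metabolism and as few as 2 for some lists. A different question was put with fry (statmod 1.5.0), on members filled on all 10 arrays. It tests a list against no change, not against other genes. Not tested for want of members were ketone body metabolism, cholesterol synthesis, heat shock proteins, the circadian clock, and endothelial, bile duct, red cell, adipose, pancreas and muscle markers.

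Genes are named by a rule fixed beforehand. Per contrast it takes the 10 largest rises and the 10 largest falls among called genes with a symbol and no overlap between the arrays of the 2 groups, up to 4 members with the smallest p of each list that passed, and 35 marker genes wherever they could be tested. Of these markers 25 have a spot and 5 could be tested (Alb, Cidec, Fasn, Pklr and Scd1).

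The pipeline was tested on simulated arrays with the same missing cells and 3558 genes. Of 100 genes changed by 1 log2 unit it recovered 97 between high-fat and control, 90 between fasted and high-fat and 94 between fasted and control, and of 100 changed by 2 log2 units it recovered 100 in each contrast. It made 16, 4 and 9 false calls in these contrasts and 0 calls in data with no change. The simulated noise was independent between genes and had the same spread on all arrays, which the real arrays do not share. These counts are therefore not error rates for the real data.

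The alternatives tried were values as deposited, quantile normalisation, scaling to a common spread, other filters on missing or low values, separate spots, other variance models, 2 groups only, the replicate number as a block, a threshold of 0.1, and each array left out in turn. Added after the data were seen were the fit with all 11 arrays, centring on the spots filled on all 10 arrays, and subtraction of the median of neighbouring spots (within 3 print rows and columns, with 20 spots per print row, a layout inferred from the order of the table). Figures were drawn with matplotlib 3.10.9, and tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.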

Results

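Liver RNA of mice on chow, on a high-fat diet, or on the high-fat diet followed by a 48 h fast was measured on 2-colour arrays against a common mouse reference RNA. A value is the log2 ratio of liver over reference, so a change between groups does not depend on the reference. Between 3864 and 5567 spots per array held a value, and 3558 genes could be tested on 10 arrays (4 control, 3 high-fat, 3 fasted). These 10 arrays correlated with each other over shared spots with a Pearson r between 0.69 and 0.94, with a median of 0.86 within groups and 0.82 between groups. High-fat array 4 had r between -0.03 and 0.01 with the others and was not used in the comparisons.

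**Figure D1:**
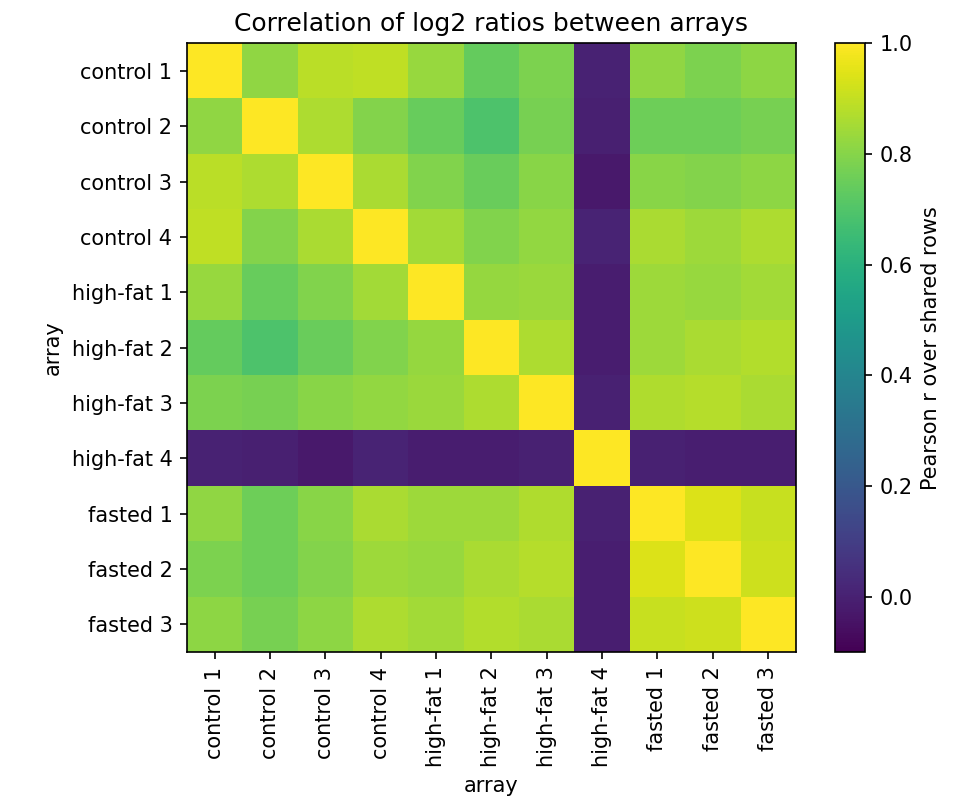
Pearson r of the log2 ratios between each pair of the 11 arrays, over the spots that both hold, with arrays ordered by group on both axes and colour giving r. High-fat array 4 stands apart from all others, with r from -0.0267 to 0.0088.

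The first comparison asks what 10 weeks of the high-fat diet changed against chow. After the diet, 3 cytochrome P450 enzymes that metabolise drugs and steroids were lower: Cyp3a11 by 3.95-fold, Cyp2c37 by 3.60-fold and Cyp2c29 by 3.30-fold. Mcts1, a factor of translation re-initiation, was 6.13-fold higher, and Pik3cg, a catalytic subunit of phosphoinositide 3-kinase found mainly in leukocytes, was 3.59-fold higher. As groups, xenobiotic metabolism genes and hepatocyte markers had medians of -0.50 and -0.60 with centred arrays, which turned to 0.00267 and 0.009 with quantile normalisation, and the hepatocyte median to 0.13 with scaled arrays. The median of all genes was 0.11 with quantile normalisation. None of these groups passed with an estimated correlation (adjusted p of 0.483 or more). In all 175 of 3558 genes were called, of which 105 rose and 70 fell, and 896 had an unadjusted p under 0.05.

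Xenobiotic metabolism was the list with the smallest p between high-fat and control in the test with a preset correlation. Of its 23 measured members 18 were lower and 5 fell (9 fell adjusted over the list alone, 0 rose), with a median log2 change of -0.50 that turned to 0.00267 with quantile normalisation and was -0.16 without control array 2, on which the list lay 0.92 above its mean, against 0.15 to 0.22 on the other control arrays. With quantile normalisation the median of all genes was 0.11, and the list still passed with the preset correlation. The preset-correlation test gave an adjusted p of 1.09e-05, against an adjusted p = 0.483 with an estimated correlation, and over all settings it ran from 2.40e-08 to 0.483. By fry, which tests 13 of the members against no change, the adjusted p was 0.206. Cyp3a11 went from 3.25 ± 0.91 (SD, n = 4) in control to 1.27 ± 0.31 (n = 3) in high-fat livers, a log2 change of -1.98 ± 0.41 (SE). Cyp2c37 changed by -1.85 ± 0.31 (SE) and Cyp2c29 by -1.72 ± 0.29 (SE), with adjusted p of 0.0132 and 0.0147. Aldh1a1, which oxidises retinal to retinoic acid, changed by -1.53 ± 0.32 (SE, adjusted p = 0.0253). The fifth member that fell was the carboxylesterase Ces1c, at -1.43 ± 0.34 (SE), which lies outside the naming rule and was chosen after its value was seen. Without high-fat array 2, Cyp2c37 and Cyp2c29 no longer passed, with adjusted p of 0.0516 and 0.0623. Cyp3a11 and Aldh1a1 were lost without control array 3 or any 1 high-fat array, with adjusted p of at most 0.0891 and 0.116 over all settings.

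The hepatocyte marker list, which holds secreted plasma proteins and liver enzymes, was lower in high-fat livers for 13 of 13 members, with a median of -0.60 that turned to 0.13 when arrays were scaled to a common spread and to 0.00903 with quantile normalisation. Without control array 2 it was -0.32, and the list lay 1.14 above its mean on that array, against 0.04 to 0.30 on the other control arrays. Of these members 2 fell, Cyp3a11 and Apoa1, the main apolipoprotein of high-density lipoprotein (4 fell adjusted over the list alone). Its adjusted p was 7.67e-05, with an adjusted p = 0.483 with an estimated correlation, 0.237 by fry, and a range over all settings of 5.93e-07 to 0.601. Apoa1 changed by -1.01 ± 0.26 (SE), with an adjusted p of 0.0480, and lost its call without each single array other than control array 4 (adjusted p up to 0.246 over all settings). Cyp2e1, the ethanol-metabolising P450, and Trf, the iron carrier transferrin, had changes of -0.64 and -0.59 without passing (adjusted p of 0.0717 and 0.108). Alb, the albumin gene, had -0.69 (adjusted p = 0.145). Markers of other cell types, 29 genes in all, had a mean change of 0.12, with an exact permutation p of 0.0571, and of 0.06 with arrays scaled, with an exact permutation p of 0.400. Of these lists, the macrophage and Kupffer cell markers had a median of 0.28 and an adjusted p of 0.582.

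The list of acute phase, complement and coagulation proteins had 14 of 16 members lower in high-fat livers. Its median was -0.42 and its adjusted p 0.0109, against 0.766 with an estimated correlation, in a range of 8.94e-04 to 0.766 over all settings. By fry, which tests 13 of the members against no change, the adjusted p was 0.644. The median was -0.06 with quantile normalisation (adjusted p = 0.240) and -0.09 with scaled arrays (adjusted p = 0.462). None of its members passed over all genes (0 rose, 0 fell), and 7 fell and 2 rose adjusted over the list alone. It shares 6 tested genes with the hepatocyte markers, and without them its adjusted p was 0.296. It was 0.584 without control array 2, with a median of -0.16, and 0.0507 without high-fat array 2. The members with the smallest p moved both ways: C-reactive protein (Crp) had -0.77 and plasminogen (Plg) -1.44, while serum amyloid Saa2 had 0.44 and the complement subunit C1qc 0.50, with adjusted p between 0.0656 and 0.0908.

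Beside all 3 lists and the single genes called for the diet stands a difference in the spread of the arrays. The median absolute deviation of the ratios was 0.40 to 0.53 on the high-fat arrays, 0.64 to 0.70 on control and 0.62 to 0.71 on fasted arrays. Across genes, which are not independent replicates, the high-fat minus control change fell with the mean level, with a slope of -0.24 and r of -0.42. With arrays scaled to a common spread the slope was 0.11. For the fasted minus high-fat change the slope was 0.25 with r of 0.54, and -0.09 with arrays scaled. Of the 175 genes called for the diet, 80 were also called with arrays scaled and 91 with quantile normalisation. The direction was kept for 172 and 173 of the 175. Some single calls may therefore rest on the smaller spread, which was not tested gene by gene.

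**Figure D2:**
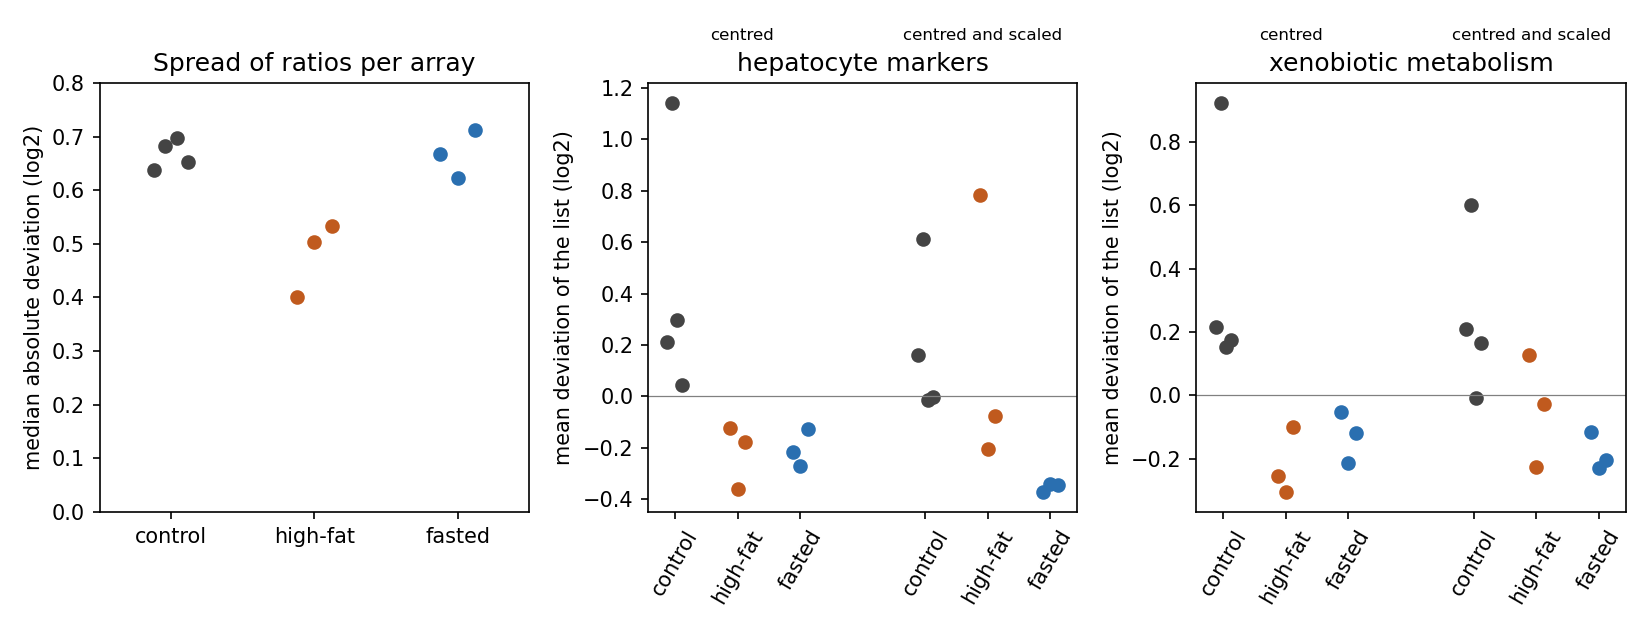
The left panel gives the median absolute deviation of the log2 ratios, 1 point per array, and the other panels give the mean log2 deviation of the hepatocyte and xenobiotic lists on each array, with arrays centred and with arrays also scaled to a common spread. The high-fat arrays have the smallest spread (0.40 to 0.53), and scaling takes the mean high-fat minus control change of the hepatocyte list from -0.65 to -0.02 (-0.33 without high-fat array 1, but 0.17 and 0.10 without high-fat arrays 2 and 3 and 0.12 without control array 2), where its median turns to 0.13. It takes the mean of the xenobiotic list from -0.59 to -0.28, where its median is -0.05. With quantile normalisation, not drawn here, the xenobiotic median is 0.00267 and that of all genes 0.11.

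Among the other 20 lists none passed between high-fat and control, with adjusted p of 0.106 or more. Amino acid breakdown passed under 4 other settings (adjusted p from 0.00185) and apolipoproteins under 1 (0.0342). Fatty acid oxidation and PPAR alpha targets had a median of -0.02 over 9 members (-0.18 to 0.10 over all settings), fatty acid and triglyceride synthesis -0.31 over 8 (-0.38 to -0.02), lipid droplet genes -0.29 over 4 (-0.36 to -0.12) and apolipoproteins -0.42 over 10 (-0.61 to 0.02). Amino acid breakdown and the urea cycle had -0.45 over 10 members (-0.60 to 0.03), bile acid genes -0.09 over 6 and gluconeogenesis -0.09 over 7. Median, mean and test differed in sign for 3 of these lists, the proteasome, the growth hormone axis and oxidative phosphorylation. The lipogenic enzymes Fasn and Scd1 had changes of -0.40 and 0.17, the lipid droplet protein Cidec -0.26 and liver pyruvate kinase Pklr 0.03, all with adjusted p of 0.294 or more.

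The largest rises were in genes outside the lists. Mcts1 rose by 2.61 ± 0.52 (SE, adjusted p = 0.0248) on the log2 scale, from 1.52 ± 0.93 (SD, n = 4) to 4.14 ± 0.88 (n = 2). Pik3cg went from -1.05 ± 0.10 (SD, n = 3) to 0.79 ± 0.38 (n = 3), a rise of 1.84 ± 0.18 (SE, adjusted p = 0.00206), and Crabp1, a carrier of retinoic acid, from 0.32 ± 0.23 (n = 3) to 1.78 ± 0.17 (n = 3), a rise of 1.46 ± 0.15 (SE, adjusted p = 0.00206). The spots of Pik3cg and Crabp1 touch each other and a called spot with no gene name on the array, and the other spots around them had mean changes of 0.45 and 0.43. Sh3kbp1, an adaptor of receptor endocytosis, rose by 1.26 ± 0.16 (SE, adjusted p = 0.00397) and Rnf148, a RING finger protein, by 1.17 ± 0.14 (SE, adjusted p = 0.00259). Cts3, a cathepsin of the placenta, and Lrrc18, a leucine-rich repeat protein, rose by 1.20 and 1.21. The GABA receptor subunit Gabrr1 rose by 1.23, the receptor phosphatase Ptpru by 1.12 and the uncharacterised 1700013F07Rik by 1.26, with adjusted p between 0.0248 and 0.0268. Ptpru held values on only 2 high-fat arrays.

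Falls outside the lists were led by Dusp12, a dual-specificity phosphatase, at -1.71 ± 0.40 (SE), and Nrbp1, a pseudokinase, at -1.58 ± 0.40 (SE), with adjusted p of 0.0370 and 0.0465. Rgs3, which shortens G-protein signals, fell by 1.57 ± 0.22 (SE, adjusted p = 0.00629), from 2.23 ± 0.44 (SD, n = 4) to 0.66 ± 0.11 (n = 3). Kcnk7, of a potassium channel family, Ndrg2, of the N-myc downstream-regulated gene family, and the zinc finger gene Zfp474 fell with changes of -1.44, -1.49 and -1.49 (adjusted p between 0.0147 and 0.0297). Ndrg2 and Zfp474 each held values on only 2 high-fat arrays, with the same value on these arrays. Of the 21 named genes called here, 7 were called under every setting that tested them (Crabp1, Cts3, Lrrc18, Pik3cg, Rgs3, Rnf148 and Sh3kbp1), and 14 were lost without at least 1 single array. Cts3, with values on 2 control arrays, was not tested when either of these was left out. Cts3, Pik3cg and Crabp1 were not tested where a value on all arrays was required.

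The groups did not overlap for 905 genes, or 25.4%, against 9.19% expected by chance from the number of values per gene. With all 11 arrays 117 genes were called (74 rose, 43 fell), and the 105 to 70 balance of rises and falls turned to 55 and 82 when arrays were centred on the spots filled on all 10, to 35 and 51 with values as deposited, to 54 and 61 with the genes of lowest mean ratio left out and to 27 and 36 after subtraction of the median of neighbouring spots, while rises led more with quantile normalisation (137 and 22) and with scaled arrays (101 and 24). The count was 100, 22 (11 rises, 11 falls) and 34 (16, 18) without high-fat arrays 1, 2 and 3, 101 (49, 52) and 55 (25, 30) without control arrays 1 and 3, 113 and 116 without fasted arrays 1 and 2, and 23 (8, 15) with the fasted arrays left out of the fit, so single arrays turned the balance as well.

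**Figure D3:**
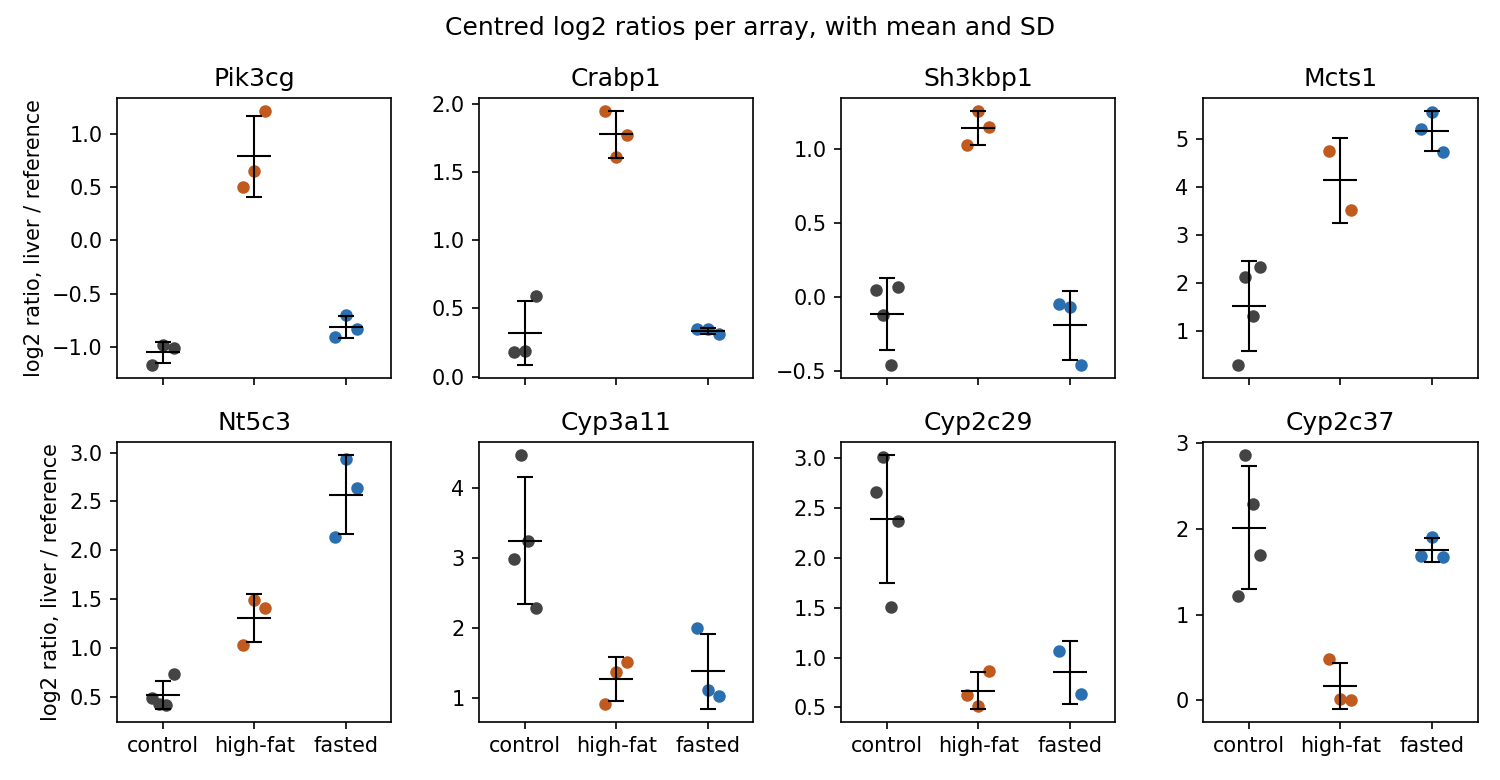
Centred log2 ratios of liver over reference for 8 named genes, 1 point per array by group, with bars for the mean and SD. Pik3cg, Crabp1 and Sh3kbp1 are higher on all 3 high-fat arrays than on any control or fasted array, and Cyp3a11, Cyp2c29 and Cyp2c37 are lower on the high-fat than on the control arrays.

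The second comparison isolates the fast, since both groups had eaten the high-fat diet. After 48 h without food, 3 genes rose and 10 fell. Psmd11, a subunit of the proteasome lid, rose by 1.75-fold, and Nt5c3, a nucleotidase that acts on pyrimidine nucleotides, by 2.40-fold as the average of 2 spots, though its 1 fully filled spot was not called. Most genes that fell had risen with the diet: Pik3cg fell by 1.60, Crabp1 by 1.44 and Sh3kbp1 by 1.34 on the log2 scale, back to ratios within 0.24 of control. None of the 23 tested lists passed, those of fat, glucose and amino acid metabolism among them, while 520 genes had an unadjusted p under 0.05.

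Nt5c3 went from 1.31 ± 0.25 (SD, n = 3) on the diet to 2.57 ± 0.40 (n = 3) after the fast, a change of 1.26 ± 0.20 (SE, adjusted p = 0.0368), and was the 1 gene called in all 3 contrasts. Its value averages 2 spots, of which 1 is filled on 5 of the 10 arrays, and the spot filled on all 10 had a change of 0.74 with the fast (adjusted p = 0.384) and of 1.30 with the diet (adjusted p = 0.0593). Psmd11 rose by 0.81 ± 0.15 (SE, adjusted p = 0.0462) as the average of 2 spots, which had 0.84 (adjusted p = 0.0441) and 0.78 (adjusted p = 0.203). With the diet the same spots moved opposite ways, by -0.68 (adjusted p = 0.0213) and 0.52 (adjusted p = 0.20). Against control the fasted livers had 0.16 on the first spot and 1.30 on the second. The other gene that rose has no name. Pik3cg, Crabp1 and Sh3kbp1 fell with adjusted p of 0.00466, 0.00462 and 0.00565, and as above the spots of Pik3cg and Crabp1 touch. Ndp, the Frizzled ligand norrin, fell by 1.25 ± 0.21 (SE), Lrrc18 by 1.18 ± 0.21 (SE) and Smtnl1, a smoothelin-like muscle protein, by 1.07 ± 0.19 (SE). Cts3 fell by 0.97, Serpina5, the inhibitor of activated protein C, by 0.89, and Pdzk1ip1, a small membrane protein of epithelia, by 0.69, with adjusted p between 0.0442 and 0.0462. Of these genes, 9 had risen between control and high-fat, in a contrast that holds the same high-fat arrays with the opposite sign: Crabp1, Cts3, Lrrc18, Ndp, Pik3cg, Serpina5, Sh3kbp1, Smtnl1 and 1 spot with no name.

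Fatty acid oxidation and PPAR alpha targets had 8 of 9 members lower after the fast, with a median of -0.25 (-0.30 to -0.05 over all settings) and an adjusted p of 0.582, and 0 of them rose or fell. Fatty acid and triglyceride synthesis had a median of -0.09 over 8 members, with an adjusted p of 0.926. Gluconeogenesis had 0.08 over 7 members (adjusted p = 0.834) and amino acid breakdown and the urea cycle 0.09 over 10, of which 9 were higher (adjusted p = 0.582, and 1 rose and 1 fell adjusted over the list alone). By the estimated correlation and by fry 0 lists passed as well. Median, mean and test differed in sign for 5 lists: the proteasome, the tricarboxylic acid cycle, the acute phase proteins, glycolysis and the cell cycle. Scd1, which desaturates stearate, had the lowest value among the fixed markers, -0.91 ± 0.32 (SE, adjusted p = 0.241). Cidec had 0.34 (adjusted p = 0.326) and Fasn 0.05. Many fasting genes, such as Pdk4, Fgf21, Pck1 and Angptl4, held a value on 0 of the 10 arrays and could not be tested.

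The groups did not overlap for 1026 genes, or 28.8%, against 12.9% by chance. With all 11 arrays 3 genes were called, all of which fell, and values as deposited gave 11 rises and 5 falls, so the balance of directions turned, while falls led with quantile normalisation (3 and 21) and with scaled arrays (0 and 15). Of the 11 named genes called here Crabp1, Pik3cg and Sh3kbp1 were called under every setting that tested them. As above, Crabp1 and Pik3cg were not tested where a value on all arrays was required. Each single array moved the count, which was 4, 3 and 4 without high-fat arrays 1, 2 and 3, 6, 3 and 5 without fasted arrays 1, 2 and 3, and 7, 23, 7 and 6 without control arrays 1, 2, 3 and 4.

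The changes with the diet and with the fast were set against each other across genes. Both contrasts share the high-fat arrays with opposite signs, so a negative correlation arises with no effect at all. The observed Pearson r was -0.40, against a mean of -0.54 (-0.58 to -0.47) in 100 simulations with no change, Spearman's rho was -0.43 against -0.51, and the covariance was -0.0459 against -0.0219. The r was thus weaker than simulated and the covariance stronger. The simulated noise had the same spread on all arrays, unlike the real arrays. It also lacks their opposite slopes on the mean level, -0.24 for the diet and 0.25 for the fast. The comparison therefore cannot tell whether the fast reversed changes of the diet.

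The third comparison sets fasted mice on the high-fat diet against fed mice on chow, so that diet and fast act together in it. Mcts1 was 12.6-fold higher than in control, Cct6b, a subunit of the cytosolic chaperonin, 6.84-fold, and Copz2, a coat protein of Golgi vesicles, 4.59-fold. Cyp3a11 was 3.66-fold and Cyp2c29 2.90-fold lower, as was Ttr, the thyroxine carrier transthyretin, by 2.60-fold. In all 114 genes were called, of which 77 rose and 37 fell, and 726 had an unadjusted p under 0.05.

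Hepatocyte markers were lower for 12 of 13 members in fasted than in control livers, and 2 fell, Ttr and Cyp3a11 (5 fell adjusted over the list alone), with a median of -0.50 that lay between -0.69 and -0.17 over all settings, the last without control array 2 (adjusted p = 0.0327). The adjusted p was 2.26e-04, with an adjusted p = 0.528 with an estimated correlation and 0.237 by fry, in a range of 5.93e-07 to 0.528 over all settings. Ttr went from 2.62 ± 0.28 (SD, n = 4) to 1.24 ± 0.12 (n = 3), a change of -1.38 ± 0.24 (SE, adjusted p = 0.0216). The apolipoproteins Apoa1 and Apoa2 had -0.91 and -0.84 without passing (adjusted p of 0.0814 and 0.0823). The 29 markers of other cell types had a mean change of 0.10, with an exact permutation p of 0.0571.

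Xenobiotic metabolism had 19 of 23 members lower in fasted than in control livers, and 2 fell (6 adjusted over the list alone), with a median of -0.31 (-0.52 to -0.11 over all settings, the last without control array 2). Its adjusted p was 4.95e-04, with an adjusted p = 0.588 with an estimated correlation and 0.385 by fry, in a range of 1.43e-06 to 0.588 over all settings, with 0.0586 when fasted array 2 was left out. Cyp3a11 changed by -1.87 ± 0.41 (SE) and Cyp2c29, with values on 2 fasted arrays, by -1.54 ± 0.33 (SE), with adjusted p of 0.0336 and 0.0346. The glutathione transferases Gstm3 and Gsta3 had -0.98 and -1.28 (adjusted p of 0.0583 and 0.0912). Acute phase, complement and coagulation genes had 13 of 16 members lower with a median of -0.44 (-0.62 to -0.17 over all settings) and an adjusted p of 0.0305, with an adjusted p = 0.788 with an estimated correlation and 0.577 by fry, in a range of 8.22e-04 to 0.788 over all settings. Of these 1 fell, Ttr (1 adjusted over the list alone). With quantile normalisation the list's adjusted p was 0.157 and with scaled arrays 0.204. Without the genes shared with the hepatocyte list the adjusted p was 0.546, without control array 2 it was 0.632, with a median of -0.17, and without fasted array 2 it was 0.0990. In this list Alb had -0.77, Crp -0.61 and Trf -0.48.

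Of the other 20 lists none passed between fasted and control (adjusted p of 0.139 or more), though amino acid breakdown did with no filter (0.00517) and apolipoproteins with values as deposited (0.0342), and median, mean and test differed in sign for 6: bile acid genes, glycolysis, the proteasome, antioxidant defence, the tricarboxylic acid cycle and the lysosome. Fatty acid oxidation and PPAR alpha targets were lower for 9 of 9 members, with a median of -0.18 (-0.29 to -0.0033 over all settings) and an adjusted p of 0.346. Fatty acid and triglyceride synthesis was lower for 7 of 8, with a median of -0.32 (-0.52 to -0.14) and an adjusted p of 0.139, and Scd1 in it had -0.74 (adjusted p = 0.201) and Fasn -0.35. Cytosolic ribosomal proteins had a median of -0.10 over 14 members (-0.20 to 0.10) and an adjusted p of 0.275, and 2 of them fell.

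Among genes outside the 3 lists that passed, the largest rises exceeded the largest falls. Mcts1 went from 1.52 ± 0.93 (SD, n = 4) to 5.18 ± 0.42 (n = 3), a rise of 3.65 ± 0.46 (SE, adjusted p = 0.00644), and Cct6b from -0.04 ± 0.26 (n = 3) to 2.74 ± 0.33 (n = 3), a rise of 2.77 ± 0.35 (SE, adjusted p = 0.00644). Nt5c3 rose by 2.05 ± 0.19 (SE), with the smallest adjusted p, 4.96e-04, and its fully filled spot by 2.03 (adjusted p = 0.0198). Copz2 rose by 2.20, the synaptic scaffold Dlg4 by 2.05, the membrane collagen Col25a1 by 1.83, Gabrr1 by 1.67, the pancreatic protease Ctrl, of the untested list of pancreas markers, by 1.54, elastin (Eln) by 1.46 and the Fos-family factor Fosb by 1.38, with adjusted p between 0.0169 and 0.0460. Jak3, a kinase of cytokine receptors in lymphocytes, fell by 1.17 ± 0.15 (SE, adjusted p = 0.00644). Ovol2, a zinc finger factor of epithelia, fell by 2.83-fold, Rplp1, a protein of the ribosomal stalk and of the ribosomal list above, by 1.37 on the log2 scale, Papss1, which makes the sulfate donor, by 1.29, Phyh, which starts the oxidation of phytanic acid, by 1.29, Has3, a hyaluronan synthase, by 1.21 and Hemk1, a methyltransferase, by 1.20, with adjusted p between 0.0219 and 0.0452. Cct6b, Jak3, Mcts1 and Nt5c3 were called under every setting that tested them, and the other 16 of the 20 named genes called here were lost without at least 1 single array. Jak3 and Mcts1, each with values on 2 high-fat arrays, were not tested when either of these was left out. Hemk1 held values on only 2 control arrays. Jak3, Mcts1 and Cct6b were not tested where a value on all arrays was required.

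The groups did not overlap for 790 genes, or 22.2%, against 8.65% by chance. With all 11 arrays 25 genes were called (17 rose, 8 fell), and with arrays scaled to a common spread 10. Values as deposited gave 198 (180 rises, 18 falls). They put the median of all genes at 0.21 in this contrast (0.015 with centred arrays) and at 0.16 between fasted and high-fat (-0.05 with centred arrays). The balance of 77 rises to 37 falls was 69 to 11 with quantile normalisation and turned to 39 and 52 when arrays were centred on the spots filled on all 10. The count was 7, 5 and 70 without fasted arrays 1, 2 and 3, 54 and 74 without control arrays 1 and 3, and 72 without high-fat array 3.

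Over all 3 groups 205 genes passed the F test, and 56 with all 11 arrays. For 41 genes with 2 tested spots the changes of the 2 spots correlated across genes with a Pearson r of -0.05 between high-fat and control, 0.44 between fasted and high-fat and -0.09 between fasted and control, with Spearman's rho of -0.05, 0.11 and -0.08, permutation p of 0.757, 0.00630 and 0.556 for r, and 0 genes called in both spots. Apart from Nt5c3 and Psmd11, each named change was measured on 1 spot.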

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

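The tests of the order of the table and of a mislabelled sample were chosen after the correlations between arrays had been seen.

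In 51 sets of 4 values, each 1 measure over the control or the high-fat arrays, 2 values lay far from the other 3. Chance alone puts about 1 in 20 independent sets there. These sets come from the same arrays and are not independent, so that rate does not apply to them directly. The deposited median of high-fat array 1 was 0.15, where the other high-fat arrays had 0.29 to 0.31, and centring removes this difference. The highest correlation of high-fat array 4 with any other array was 0.0088, where the other high-fat arrays had 0.848 to 0.877.

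The values of high-fat array 4 did not correlate with those of the other 10 arrays. A mislabelled mouse sample in the usual order of spots is argued against by the highest r of 0.0088, since livers and other mouse tissues set against 1 reference RNA would keep some correlation. Along 20 successive segments of this array the share of filled spots followed the share along the 20 print columns of the other arrays, with a Pearson r of 0.931, Spearman's rho of 0.941 and a permutation p of 1e-05, the smallest that the permutations can give, while the segments of the other arrays gave r from -0.07 to 0.24. A candidate explanation is therefore that its values are listed in another order of spots, which stays a hypothesis, since the order could not be restored. No biological explanation was tested.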

How the results depend on the processing

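Chosen after the data had been seen were the fit with all 11 arrays, centring on the spots filled on all 10 arrays, subtraction of the median of neighbouring spots, and array weights for the correlation of diet and fast. All other alternatives were fixed before the data were examined. A planned filter on all 11 arrays became one on all 10, and a check with separate high-fat arrays for the 2 contrasts was not run. The cause was not tested for any result below that did not keep, except where fewer genes or arrays were tested by construction.

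Of 52 named calls 14 were kept under every setting that tested the gene, 38 were lost under at least 1 and 0 changed direction. Of the values that did not pass, 12 of 27 named values and 4 of 63 list tests did so under at least 1 setting, the threshold of 0.1 among them. The main counts are 175 between high-fat and control, 13 between fasted and high-fat, 114 between fasted and control, 205 by the F test and 6 list tests. Values as deposited called 86 for the diet (80 of the 175) and 198 between fasted and control, with the median of all genes at 0.21 there. Quantile normalisation called 24 for the fast and let 3 lists pass, with the median of all genes at 0.11 for the diet. There the medians for the diet turned to 0.00903 for hepatocyte markers (adjusted p = 0.240, range 5.93e-07 to 0.601) and to 0.00267 for xenobiotic metabolism (adjusted p = 0.00530, range 2.40e-08 to 0.483). Scaling to a common spread called 10 between fasted and control and 88 by the F test, let 3 lists pass, moved the correlation of diet and fast from -0.399 to -0.466, and turned the hepatocyte median for the diet to 0.13 (adjusted p = 0.601, range 5.93e-07 to 0.601).

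With a value required on all arrays 7 genes were called for the fast, and with no filter 3, with 111 by the F test. Without the genes of lowest mean ratio 115 were called for the diet and the correlation was -0.306. Array weights called 118 for the fast, 232 between fasted and control and 406 by the F test. Fits to the 2 groups of a contrast called 23 for the diet, 53 for the fast and 57 between fasted and control. An adjusted p under 0.1 gave 464, 46, 255 and 493. With all 11 arrays 3 genes were called for the fast, 25 between fasted and control and 56 by the F test, and the correlation was -0.520. With the median of neighbouring spots subtracted the counts were 63 for the diet (48 of the 175 main calls among them), 48 between fasted and control and 82 by the F test. With centred arrays, changes of spots next to each other in a print row correlated across the array. The r was 0.23 for the diet, 0.10 for the fast and 0.15 between fasted and control, against 0.035, 0.005 and 0.02 after shuffling. After the subtraction it was 0.06, 0.05 and 0.02. The cause of this likeness of neighbouring spots was not tested. With an estimated correlation 0 list tests passed in camera, against 6 with the preset correlation. By fry 0 passed as well. That count is not comparable with the 6, since fry tests against no change and only on members filled on all arrays of the fit.

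No pairing of mice by replicate number was seen. After their group means were removed, arrays of the same number correlated with r from -0.18 to 0.18, and arrays of different numbers with r from -0.23 to 0.25. So few pairs cannot exclude a shared batch. With that number as a block 4 genes were called for the fast and 115 by the F test, and the correlation was -0.331.

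Without 1 array at a time the counts ran from 22 to 190 for the diet, 3 to 23 for the fast, 5 to 157 between fasted and control and 49 to 206 by the F test, with 4 to 7 list tests and a correlation of -0.474 to -0.353. The lowest counts came without high-fat array 2 (22), without fasted array 2 or high-fat array 2 (3), without fasted array 2 (5) and without fasted array 2 or high-fat array 3 (49). The F test count was also 66 and 76 without control arrays 1 and 3, 70 and 99 without fasted arrays 1 and 3, and 127 and 81 without high-fat arrays 1 and 2. Intensities are not used here, so what signal over background limits is unknown.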

Other observations

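The print-block test and the splits of the genes called up by the diet and down by the fast were set before their results were seen, and the other tests in this part, the block size of 27 print rows among them, were chosen after.

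Some called genes outside the naming rule, chosen after their values were seen, belong to fixed lists. Between fasted and control the macrophage scavenger receptor Cd163 rose by 0.66 (adjusted p = 0.0487), the endothelial growth factor receptor Kdr by 0.90 (adjusted p = 0.0181) and the liver phosphofructokinase Pfkl by 1.07 (adjusted p = 0.0275). The ribosomal protein Rpsa fell by 1.16 (adjusted p = 0.0358) and the proteasome subunit Psmb5 by 0.72 (adjusted p = 0.0422), while Psmd11 of the same list rose by 0.73 (adjusted p = 0.0219) as the average of spots with 0.16 and 1.30. Rplp1 was lower for the diet as well, at -1.18 ± 0.28 (SE, adjusted p = 0.0408).

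Spots filled on all arrays of 1 group and on none of the other numbered 73 between high-fat and control, 151 between fasted and high-fat and 66 between fasted and control. The highest numbers in other splits of the same arrays were 73, 86 and 66, with 2 of 35, 1 of 10 and 2 of 35 splits as large, the real one included.

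For gene counts the real split had the most calls, which argues against chance but cannot exclude it, since 35 splits give no p under 0.0286. The real split was the 1 of 35 with as many calls between high-fat and control (175, highest other 11), the 1 of 35 between fasted and control (114, highest other 32) and the 1 of 100 for the F test (205, highest other 45). Between fasted and high-fat the 10 splits are too few (13, highest other 0, the real one being the 1 with as many). For the lists the real split did not stand out: 21 of 35 splits let at least 3 lists pass between high-fat and control (highest other 9), and 24 of 35 did so between fasted and control (3, highest other 7). Between fasted and high-fat the real count was 0 lists by camera and 0 by fry (highest other 2 by camera), so all 10 of 10 splits are as large by construction, while 520 genes had an unadjusted p under 0.05.

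The lower hepatocyte, xenobiotic and acute phase lists between high-fat and control come with a smaller spread of ratios on the high-fat arrays. With all arrays scaled to a common spread the mean changes were -0.02, -0.28 and -0.06, with exact permutation p of 0.886, 0.171 and 0.771, and they depend on single arrays: they were -0.33, -0.36 and -0.23 without high-fat array 1, 0.17, -0.19 and 0.08 without high-fat array 2, and 0.12, -0.14 and 0.10 without control array 2. With centred arrays the exact permutation p was 0.0571, 0.0286 and 0.143. The smaller spread may account for much of the hepatocyte and acute phase shifts, whose means went from -0.65 and -0.40 to -0.02 and -0.06. Without high-fat array 1 they went from -0.70 and -0.43 to -0.33 and -0.23, so a part of each was left there. For the xenobiotic list the tables do not decide, with camera on scaled values at an adjusted p of 0.00469 (range 2.40e-08 to 0.483). Between fasted and control, whose spreads were alike, the scaled means were -0.54, -0.44 and -0.35. Their exact permutation p was 0.0286, 0.0571 and 0.0857 (adjusted over all such tests 0.102, 0.102 and 0.137). Without control array 2 these means were -0.40, -0.30 and -0.19. A lower share of hepatocyte RNA stays open, with markers of other cell types at 0.12 and hepatocyte markers at -0.65 in centred arrays, each with an exact permutation p of 0.0571. An effect of the diet stays open too, since all 3 high-fat arrays have the smaller spread and scaling would also remove a real loss of contrast.

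The 9 genes called up by the diet and down by the fast were more than in the other drawn splits, 1 of 100 having as many (highest other 1). Both contrasts hold the same high-fat arrays, so a gene that stands apart on these arrays, from whatever cause, can be called in both. The splits therefore cannot tell whether the fast reversed an effect of the diet. Of their spots 3 touch each other (Pik3cg, Crabp1 and the unnamed spot), in 3 pairs where random sets gave at most 2 (permutation p of 1e-04, the smallest the permutations can give), and the print-block test, with a permutation p of 0.0429 for 18 print rows per block (0.0420 in another draw) and 0.0972 for 27, counts only these 3 pairs. The spots around Pik3cg and Crabp1 rose by 0.45 and 0.43 with the diet, and with the median of neighbouring spots subtracted their diet changes went from 1.84 to 1.56 and from 1.46 to 1.02 and stayed called in both contrasts, which argues against a defect reaching those neighbours as the whole cause, while the unnamed spot went from 0.84 to 0.47 and lost its diet call (adjusted p = 0.114), and a defect that adds to these changes or lies in the 3 touching spots alone stays open. For the other 6 genes a local defect is argued against by a mean diet change of 0.0504 in the spots around them, against 1.04 in the genes themselves, although with that median subtracted Cts3, Ndp, Serpina5 and Lrrc18 lost the call for the fast (adjusted p of 0.0581 to 0.0923) with changes of about the same size (-1.13, -1.34, -0.84 and -1.04, before -0.97, -1.25, -0.89 and -1.18). A response of these genes to both diet and fast is a hypothesis from the same data, and other technical causes were not tested.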
